A study of Oryza sativa with 24 samples.

How the data were processed

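Gene expression was measured in rice seedlings at the 4-leaf stage, in shoot and leaf tissue, on 24 Affymetrix arrays. Per the labels' protocols, the seedlings of 8 accessions were moved to a chamber held at 4 °C with a light and dark cycle, and were sampled before the move and after 6 h and 24 h. Per the labels' protocols, total RNA was extracted with TRIzol and biotinylated cRNA was prepared for hybridisation. The deposited values were probe set intensity on a linear scale, 1 column per array. The software, summarisation and scaling that the authors used to make these values are not given in the sources used here. The medians of the 24 arrays lay between 41.8 and 46.7. The number of arrays, 1 per accession and time, limits the precision.

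The table held 57381 probe sets, of which 123 were control probe sets and were left out of every test, so that 57258 were tested. It held 4 exact zeros. Values were taken as log2(value + 32). A fold change is on this scale and understates the change of dim genes. No further normalization was applied in the fit. The annotation table given paired 22436 tested probe sets with 1 gene and 95 with several, and gave none for 34727. No gene was named from a probe set with several genes. All 22436 single-gene probe sets were found in the RefSeq gene table of assembly ASM3414082v1, which was used for names only. They covered 17905 genes, of which 2452 had a name other than a locus or clone number. A gene was represented by its probe set with the highest mean over all 24 arrays, and probe sets shared between transcripts (_x_at, _s_at) were set aside where the gene had another.

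Time point and accession were taken from the labels of each array. All 24 arrays entered 1 linear model with time point and accession as fixed terms, in limma 3.58.1 (R 4.3.3; lmFit, and eBayes with a trend of variance on intensity). Contrasts were 6 h versus before, 24 h versus before and 24 h versus 6 h, and the accession term was tested with a moderated F test. P-values were adjusted by Benjamini-Hochberg over the 57258 probe sets, and a change passed at an adjusted p under 0.05. The counts of probe sets that also changed at least 2-fold are given beside. The SD printed beside a change is that of the changes of the 8 accessions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for mapping, tables and plots.

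The accession was a block because the labels give each accession all 3 time points. This pairing was checked on the data. Deviations from the time point means were correlated across probe sets for each of the 24 pairs of arrays of an accession, and r lay between 0.248 and 0.886. Every value was above the minimum of 0.1 set for pairing, and the lowest without the mixed arrays was 0.653. Over arrays of different accessions the median was -0.11 and the highest 0.512, above the lowest pairs of Lixingeng and MH63, which hold a mixed array. The labels do not say whether the arrays or accessions came from separate plantings or pools of plants. The p-values therefore measure only the spread between these samples, with the accessions standing as the replicates of a time point.

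Gene lists were compared as follows. The mean log2 change of the measured members was taken per accession and tested with an exact two-sided sign-flip permutation test over the 8 accessions, which has 256 sign patterns and a smallest possible p of 0.00781. P-values were adjusted by Benjamini-Hochberg over the lists with at least 3 measured members and both cold times, so that the smallest adjusted p was 0.0249. The same was done separately for 24 h versus 6 h. As a competitive test, limma's camera was run with a preset correlation between genes of 0.01 and again with an estimated correlation. Counts of members that passed over all probe sets are given beside those adjusted over the list alone for the planned lists, and for the symbol families that passed at 6 h or 24 h versus before. For 24 h versus 6 h they are given over all probe sets for the lists that passed, and adjusted over the list alone for the planned ones. A list member was taken as not above the background where on none of the 24 arrays it read over the highest of the 10 control probe sets for Magnaporthe, a fungus, on the same array. This rule was set after the results were seen, and such members stayed in every count and mean.

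The 19 lists of named genes, the tests of the comparisons, the rule for named genes except for the replacement given below, and all but the 2 alternatives described at the end were chosen before the data were examined. The tests of the mixed arrays and of time of day were chosen after the results were seen. Of the 180 planned list members, 87 were measured. For 70 the symbol was not in the tables given, 16 had no single-gene probe set, 4 matched only on another chromosome and 3 were ambiguous. The lists had been written with locus identifiers that the tables did not hold, so members were matched by symbol and chromosome. Families of genes had been planned by description, and the tables held no descriptions. These were replaced by 24 families read from gene symbols, drawn up after the annotation tables were read and before any test of expression, which gave 43 lists in all. Of these, 35 had at least 3 measured members.

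Named genes were chosen by rule. For 6 h and for 24 h versus before, they were the 12 highest and 12 lowest log2 changes among genes that passed, changed in the same direction in all 8 accessions and had a name other than a locus or clone number. For 24 h versus 6 h they were the 5 highest and 5 lowest, and for the accessions the 10 with the largest F. All measured DREB1/CBF and circadian clock members were added, with up to 4 members of each other list, those with the largest changes among members that passed. The planned requirement of an informative description was replaced by a name other than a locus or clone number, because the tables given held no descriptions. In all, 146 genes were named by the rule.

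The size of the response of an accession was the slope, through 0, of its log2 changes on the mean change of the other 7, over the probe sets that passed without that accession. The overlap of 6 h and 24 h changes was set beside simulated unchanged groups that shared the before arrays (20 simulations), beside the product expected for independent lists, and beside values in which the 6 h changes came from 4 accessions and the 24 h changes from the other 4 (70 choices).

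The procedure was tested on simulated data. Of 100 probe sets changed by a log2 of 1 among 57258 at 6 h versus before, 98% were recovered, with a median estimate of 1.00 times the true change. Of 100 changed by 0.5, 94% were recovered at 1.03 times, with 11 false calls in that simulation. For differences between accessions, 93% of 100 probe sets changed by 1 and 74% of 100 changed by 0.5 were recovered, with 3 false calls. Of 200 lists of 10 unchanged genes, 2.5% had an exact sign-flip p under 0.05 before adjustment, and of 20 lists shifted by 0.2, 100% did. The noise was drawn independently for each probe set, while members of a list can vary together (estimated correlation 0.609 for DREB1/CBF factors). These list figures therefore do not give the power for the lists used here.

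Alternatives tried were quantile normalization, equal medians, other offsets (1 and 128), the brighter probe sets alone, 1 probe set per gene, no _x_at and _s_at probe sets, array weights, no variance trend, no accession block, only the arrays of the times compared, each accession left out, an adjusted p under 0.01, other probe sets of a named gene, and other summaries of a list. After the data were seen, 2 more were added: a fit without the 2 arrays that carried the signatures of 2 accessions, and a fit without both of those accessions.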

Results

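The data were 24 arrays of rice seedlings, 8 in each of 3 groups: before cold, after 6 h at 4 °C and after 24 h at 4 °C. Each group held 1 array from each of the accessions 9311, IRAT109, ZS97, Geng87-304, Youmangzaogeng, Muguanuo, Lixingeng and MH63. The mean 75th percentile of intensity was 122 before cold, 116 at 6 h and 114 at 24 h. Within accessions it was lower than before cold in 8 of 8 at 6 h (mean difference -5.63 ± 2.37, SD). It was also lower in 8 of 8 at 24 h (-8.52 ± 3.20). The log2 ratio of the 3′ to the 5′ probe sets of the actin control, a sign of RNA quality, averaged 3.52 ± 0.37 before cold, 3.48 ± 0.36 at 6 h and 3.08 ± 0.46 at 24 h (SD, n = 8). Within accessions it was lower at 24 h than before cold in 8 of 8 (-0.44 ± 0.28) and lower than at 6 h in 7 of 8 (-0.39 ± 0.34). The ratio of the EF1a control was lower at 24 h than before cold in 7 of 8 accessions and that of the GAPDH control higher in 7 of 8. A pair of arrays stood apart from the rest. The arrays labelled Lixingeng before cold and MH63 after 24 h had a Spearman correlation of 0.992 across probe sets, above every other of the 276 pairs, of which the next was 0.981. On probe sets bright in only 1 of the accessions, chosen after the pair was seen, both arrays had median levels at 0.498 to 0.585 of the accession's other arrays, for both accessions. Both also lay between the before and 24 h states of the other accessions, at 0.348 and 0.321 on a scale from 0 to 1. These arrays stayed in every main fit, and the counts of probe sets without them, an alternative chosen after seeing the data, are given beside.

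The first question was what changed within 6 h of cold. DREB1B (LOC4347618) and DREB1A (LOC4347620), transcription factors of the CBF type that act on cold-responsive promoters, had the highest rises of the named genes. DREB1B rose 22.9-fold (log2 change 4.52 ± 1.94, SD, n = 8; adjusted p = 1.18e-05) and DREB1A rose 17.5-fold (4.13 ± 1.81; adjusted p = 2.41e-05), both higher in 8 of 8 accessions, by 0.04 and 0.20 in Lixingeng. Without Lixingeng, whose before array is 1 of the mixed pair, the changes were 5.16 and 4.69. MYB2 (LOC4332651), a MYB factor of stress responses, rose 8.63-fold (3.11 ± 1.12; adjusted p = 3.53e-06). On their dimmest arrays DREB1B, DREB1A and MYB2 read 37.25, 37.1 and 12.28. These readings lay under every array median (41.8 to 46.7), so the exact folds of these genes depend on the offset. The same limit applies to other named genes with such dim readings, among them PMEI28 (28.26), NAC45 (29.69), OsTPP4 (22.87) and EXPB7 (23.36). The calmodulin-like calcium sensors CML31 and CML27 rose 5.52-fold and 4.41-fold, and EL2, an inhibitor of cyclin-dependent kinases, rose 5.49-fold. Another probe set of EL2 rose by a log2 of 1.56 and a dim one of CML27 by 0.13. The largest falls were those of CIPK5, a kinase regulated by calcineurin B-like calcium sensors, which fell by 1.71 ± 0.36 on the log2 scale (adjusted p = 2.06e-05), and of the wall-loosening beta-expansins EXPB7 and EXPB4, which fell by 1.59 ± 0.26 and 1.59 ± 0.49 (adjusted p = 9.02e-06 and 0.000267), each in 8 of 8 accessions.

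Of the other genes ranked highest at 6 h, PMEI28, a pectin methylesterase inhibitor, rose by a log2 of 1.72, the transcription factor NAC067 by 1.61, the phosphatase gene OsPP2C32 by 1.44 and AOS2, an allene oxide synthase of jasmonate synthesis, by 1.37. OsWRKY24 rose 2.82-fold. TPP1, a trehalose phosphate phosphatase, rose by 1.23, a call that was lost when any of IRAT109, Geng87-304, Youmangzaogeng or Muguanuo was left out (1.04 to 1.18). Further genes ranked lowest were the homeobox gene HOX4, which fell by 1.33, IRL1, which fell by 1.33, and EXPB11, which fell by 1.25. CYCP2-1, a cyclin of the P type, fell by 1.22, MAN1, a mannanase gene, fell by 1.21, and CIPK6 fell by 1.16. The sugar transporter gene SWEET1B fell by 1.13, WRKY51 fell by 1.04 and the glycosyltransferase gene GT43A fell by 1.03.

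Among the gene lists, 4 of the 5 measured DREB1/CBF factors rose at 6 h (4 adjusted over the list alone, and 4 without the mixed arrays), and the remaining member, DREB1C, had a log2 change of -0.03 (adjusted p = 0.818). The probe set of DREB1C read 27.3 to 52.3 over the 24 arrays, near the array medians (41.8 to 46.7). Its other probe sets averaged 5.51 and 5.52 on the log2 scale. DREB1C was not above the background at any time, so a change of this gene was not measurable here. By the same rule 90 of the 428 list members were not above the background on any array. Of these, 3 passed at 6 h, 23 at 24 h and 12 for 24 h versus 6 h, and the counts of members include them. They made up 14 of the 28 DNA replication factors and 13 of the 30 expansins and xyloglucan enzymes. DREB1G rose 6.09-fold and DREB1E 1.27-fold. The mean change of the list was 2.31 ± 1.01 (SD, n = 8; exact sign-flip test, adjusted p = 0.0322). By camera, adjusted p was 8.49e-05 with the preset correlation and 0.256 with an estimated correlation. In Lixingeng, whose before array is 1 of the mixed pair, the mean change of this list was -0.05, and DREB1B already stood at 12.14 on that array against 6.11 to 8.49 on the before arrays of the other accessions. Of the 10 measured genes of jasmonate synthesis and JAZ repressors, 6 rose and none fell (6 and 2 adjusted over the list alone; 7 and 1 without the mixed arrays). The JAZ genes, repressors of jasmonate signalling, included JAZ10 at 9.68-fold, JAZ9 at 7.58-fold and JAZ13 at 6.32-fold, each higher in 7 of 8 accessions. On their dimmest arrays DREB1G, JAZ9 and JAZ13 read 27.66, 20.69 and 8.304, under every array median, so their exact folds depend on the offset. The mean change of the jasmonate list was 1.24 ± 0.69 (exact sign-flip test, adjusted p = 0.0322; by camera, adjusted p = 0.00017 with the preset and 0.316 with an estimated correlation), with -0.37 in Lixingeng.

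Other cold and stress regulators rose in 6 of 12 members at 6 h and fell in 0 (7 and 1 adjusted over the list alone; 7 and 0 without the mixed arrays), with a mean of 0.81 ± 0.46 (exact sign-flip test, adjusted p = 0.0322; by camera, adjusted p = 0.00017 with the preset and 0.316 with an estimated correlation). WRKY71 rose 4.55-fold and MYB4 rose 5.22-fold, while another probe set of each gene changed by 0.80 and 0.28 and did not pass. Clade A protein phosphatases 2C, which act as negative regulators in abscisic acid signalling, fell in 3 of 6 members (4 adjusted over the list alone; 3 without the mixed arrays), led by PP2C68, which fell by 0.97 ± 0.42. Their mean change was -0.34 ± 0.18, lower in 8 of 8 accessions (exact sign-flip test, adjusted p = 0.0249; by camera, adjusted p = 0.0764 with the preset and 0.381 with an estimated correlation). Of the 2 measured genes of abscisic acid synthesis and breakdown, both for hydroxylases that break the hormone down, 1 rose and 1 fell (1 and 1 adjusted over the list alone). ABA8OX1 rose 11.1-fold (log2 change 3.47, and 4.06 without Lixingeng; adjusted p = 5.58e-05; higher in 7 of 8 accessions), and ABA8OX2 fell by 0.25 (adjusted p = 0.0356), a call that was lost with quantile normalization (-0.19), with equal medians (-0.24) and when any of 9311, IRAT109, ZS97, Geng87-304, Youmangzaogeng or Muguanuo was left out (-0.21 to -0.27).

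For several families read from gene symbols the mean of the members shifted at 6 h, while most members of some did not pass. Calmodulins and calmodulin-like proteins rose in 7 and fell in 2 of 26 members, with CML15 at 7.37-fold and CML16 at 5.34-fold, and a mean of 0.45 ± 0.18 (exact sign-flip test, adjusted p = 0.0249; by camera, adjusted p = 0.256 with an estimated correlation). AP2/ERF factors, which include all 5 DREB1/CBF members, rose in 5 of 10 (mean 1.23 ± 0.55; adjusted p = 0.0322 in the exact test; by camera, adjusted p = 0.256 with an estimated correlation). NAC factors rose in 4 of 8 (0.42 ± 0.26; adjusted p = 0.0322 in the exact test; by camera, adjusted p = 0.316 with an estimated correlation). Expansins and xyloglucan enzymes fell in 10 of 30 members and rose in 0 (-0.33 ± 0.07; adjusted p = 0.0249 in the exact test; by camera, adjusted p = 0.256 with an estimated correlation). Cellulose synthases fell in 5 of 9 (-0.34 ± 0.20; adjusted p = 0.0322 in the exact test; by camera, adjusted p = 0.566 with an estimated correlation), among them CESA7, which fell by 0.60. Aquaporins fell in 6 of 25 (-0.21 ± 0.12; adjusted p = 0.0249 in the exact test; by camera, adjusted p = 0.474 with an estimated correlation), and Aux/IAA proteins, repressors of auxin responses, fell in 7 of 26 (-0.17 ± 0.06; adjusted p = 0.0249 in the exact test; by camera, adjusted p = 0.381 with an estimated correlation). The Aux/IAA gene IAA10 fell by 0.48. By camera with the preset correlation, adjusted p was 0.00254 for calmodulins, 0.0002 for AP2/ERF factors and 0.0407 for NAC factors. It was 0.00658 for expansins, 0.0177 for cellulose synthases, 0.0269 for aquaporins and 0.0337 for Aux/IAA proteins, so these lists passed only with the preset. CBL-interacting kinases fell in 7 of 24 (-0.24 ± 0.09), RNA helicases of the DEAD box in 2 of 3 (-0.22 ± 0.09), histones in 3 of 5 (-0.46 ± 0.27) and tubulins in 2 of 10 (-0.17 ± 0.14), with adjusted p = 0.0249, 0.0249, 0.0322 and 0.0443 in the exact test. None of these 4 passed by camera, with adjusted p = 0.474, 0.566, 0.627 and 0.758 with an estimated correlation. The shift of tubulins no longer passed with equal medians (-0.16). Adjusted over the list alone, and without the mixed arrays after a slash, higher and lower members were 7 and 3 / 7 and 3 of the calmodulins, 5 and 0 / 5 and 0 of the AP2/ERF factors, 4 and 1 / 4 and 0 of the NAC factors and 0 and 13 / 0 and 13 of the expansins. They were 0 and 7 / 0 and 5 of the cellulose synthases, 0 and 11 / 1 and 11 of the aquaporins, 0 and 9 / 0 and 7 of the Aux/IAA proteins and 1 and 8 / 2 and 9 of the CBL-interacting kinases. They were 0 and 2 / 0 and 2 of the RNA helicases, 0 and 4 / 0 and 4 of the histones and 0 and 4 / 0 and 2 of the tubulins.

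Of the 15 lists that passed at 6 h, 8 no longer did when any 1 accession other than Lixingeng was left out. Over all 8 such fits their means were 2.20 to 2.65 for DREB1/CBF factors, 1.18 to 1.47 for jasmonate genes, 0.76 to 0.96 for other cold and stress regulators, 0.37 to 0.48 for NAC factors, 1.18 to 1.42 for AP2/ERF factors, -0.39 to -0.31 for cellulose synthases, -0.53 to -0.42 for histones and -0.20 to -0.15 for tubulins. Without Lixingeng the WRKY factors (0.45) and U-box and RING ubiquitin ligases (-0.08) passed as well. In the 8 lists that were lost, Lixingeng was the only accession of opposite sign. Fewer accessions raise the smallest exact p, so these losses do not show dependence on any 1 of the accessions left out.

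The shift of 20 lists did not pass at 6 h. The circadian clock list had a mean of 0.25 ± 0.21 (adjusted p = 0.0534 in the exact test), passed by camera at 0.0151 with the preset correlation, and had adjusted p = 0.466 with an estimated correlation. It passed the exact test with quantile normalization (0.27) and with equal medians (0.26). Its members GI and PRR95 rose by 0.36 and 0.44 (adjusted p = 0.0124 and 0.0457; 2 adjusted over the list alone). GI no longer passed without Geng87-304 (0.34), nor PRR95 without any of ZS97, Geng87-304, Youmangzaogeng, Muguanuo or MH63 (0.42 to 0.45). PRR1, PRR37, PRR73 and LHY had changes of 0.23, 0.32, 0.12 and 0.01 and did not pass. Another probe set of PRR37 rose by 0.33 and did pass (adjusted p = 0.0274, limma). Antioxidant enzymes, of which 1 of 6 rose (2 adjusted over the list alone), had adjusted p = 0.103 in the exact test, passed by camera at 0.0494 and had adjusted p = 0.478 with an estimated correlation. In LEA proteins and dehydrins, 0 of 7 members passed (0 adjusted over the list alone; list adjusted p = 0.399), as did 0 of 3 photosystem, light harvesting and Rubisco genes (0.453), 0 of 7 genes of chlorophyll synthesis (0.26), 0 of 4 of gibberellin metabolism and signalling (0.0965), 0 of 12 photosynthesis proteins (0.898) and 0 of 22 cytosolic ribosomal proteins (0.223), all by the exact test and each with 0 adjusted over the list alone. Trehalose, raffinose and proline synthesis had 1 of 4 higher (1 higher and 1 lower adjusted over the list alone; 0.132), cell division 1 of 3 lower (1 adjusted over the list alone; 0.0534) and root-preferential genes, markers of another tissue, 0 of 4 (1 lower adjusted over the list alone; 0.228). Adjusted p in the same test was 0.0746 for heat shock proteins and factors, in which 4 of 45 rose and 7 fell, 0.0798 for WRKY factors, 0.0534 for U-box and RING ubiquitin ligases and 0.0965 for glutathione S-transferases. It was 0.463 for calcium-dependent kinases, 0.0798 for DNA replication factors, 0.103 for trehalose phosphate phosphatases, 0.139 for stress-associated zinc finger proteins and 0.265 for sucrose synthases and sucrose phosphate synthases. The mean and the median of the members differed in sign for trehalose, raffinose and proline synthesis (0.23 and -0.09), WRKY factors (0.34 and -0.19), calcium-dependent kinases (0.03 and -0.01) and stress-associated zinc finger proteins (0.05 and -0.002). Camera ranked the first of these as lower, and chlorophyll synthesis, DNA replication and the sucrose enzymes as higher against means of -0.10, -0.03 and -0.06.

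In all, 5582 of 57258 probe sets (9.75%) changed at 6 h, 1599 higher and 3983 lower, and 359 of these changed at least 2-fold, 225 higher and 134 lower. Without the 2 mixed arrays the count was 8250 (2574 higher and 5676 lower). More probe sets were lower than higher, and the 75th percentile of intensity was lower than before cold in 8 of 8 accessions. With quantile normalization 45.9% of the probe sets that passed were higher, against 28.7% for the values as deposited. The count was 8854 with array weights and 1530 without the accession as a block. No untreated array at 6 h was analysed here, so time of day was not separated from cold.

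**Figure D1:**
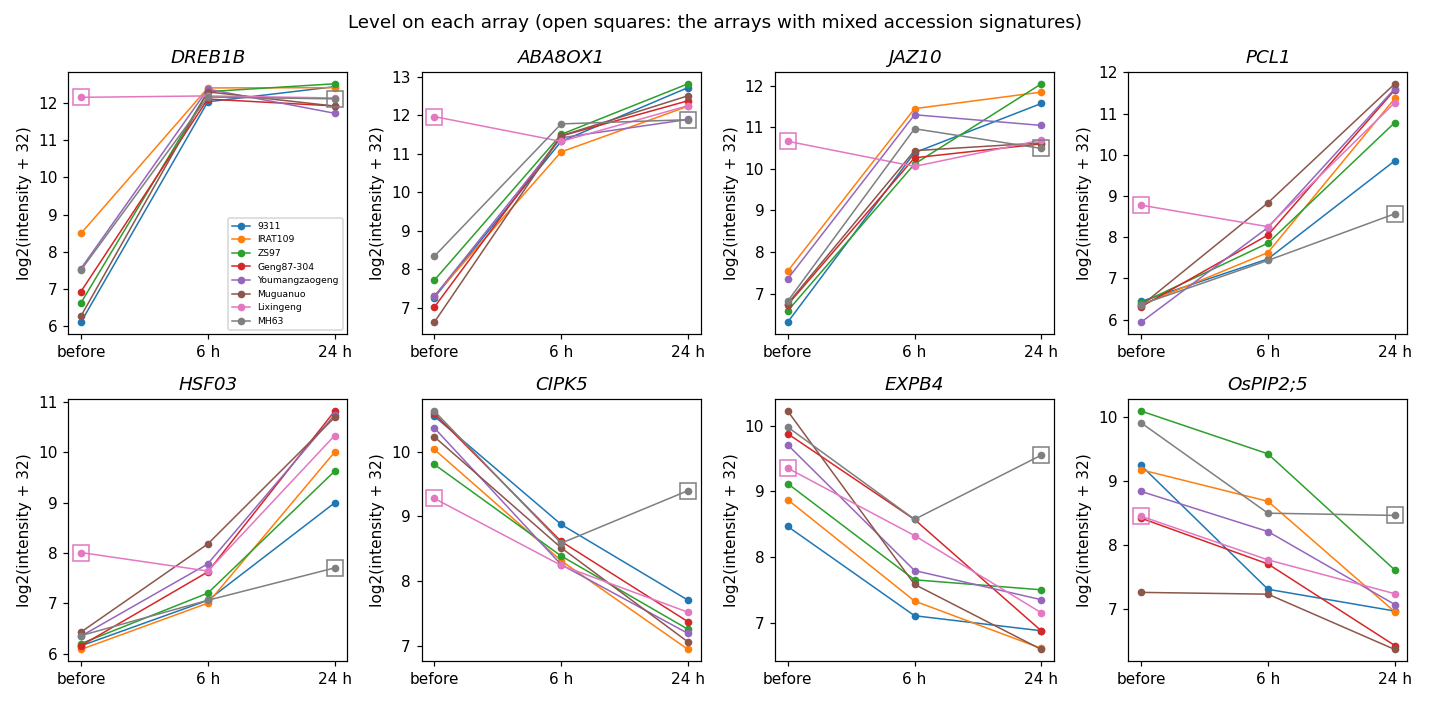
Level of 8 named genes on each of the 24 arrays, as log2(intensity + 32), against time in cold (before, 6 h and 24 h), with 1 line per accession and open squares on the 2 arrays with mixed accession signatures. DREB1B stood near 12 on all 6 h and 24 h arrays and already at 12.14 on the Lixingeng before array, and CIPK5 fell in all 8 accessions.

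**Figure D2:**
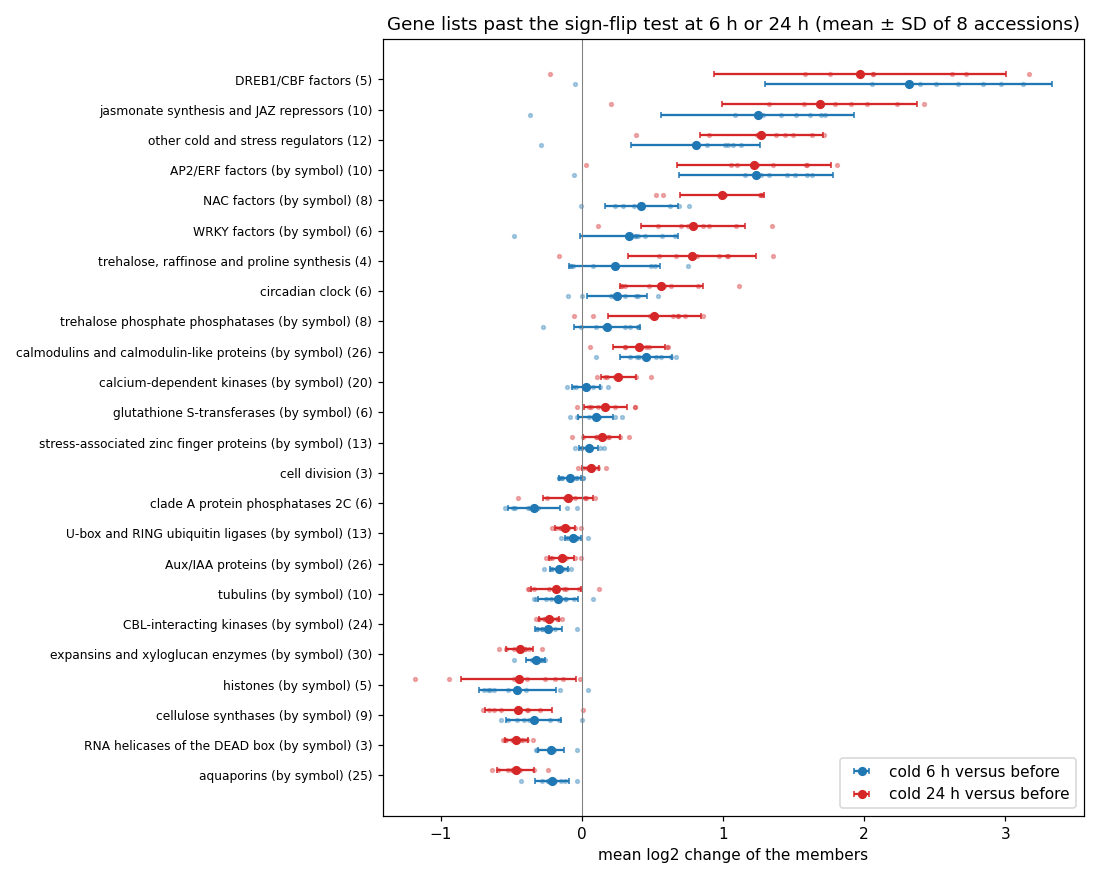
Mean log2 change of the members of each gene list that passed the exact sign-flip test at 6 h (blue) or 24 h (red) versus before, with the number of members in parentheses. Large points and bars give the mean and SD of 8 accessions and small points the single accessions, and the DREB1/CBF list had the highest means, 2.31 at 6 h and 1.97 at 24 h.

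The second question was what had changed after 24 h of cold. ABA8OX1 (LOC9269675), which breaks down abscisic acid, rose 21.0-fold (log2 change 4.39 ± 1.80, SD, n = 8; adjusted p = 5.04e-07), and PCL1 (LOC4326391), a factor of the circadian clock, rose 18.7-fold (4.23 ± 1.36; adjusted p = 4.01e-08), each in 8 of 8 accessions. JAZ10 rose 13.6-fold and the heat stress factor gene HSF03 10.5-fold, and ACA7, CML16 and OsWRKY24 rose 9.47-fold, 8.69-fold and 8.62-fold. PCL1 was not matched to the planned clock list, so the means of that list leave it out. On their dimmest arrays PCL1, HSF03, ACA7 and OsWRKY24 read 29.33, 35.95, 17.26 and 26.02. These readings lay under every array median (41.8 to 46.7), so the exact folds of these genes depend on the offset. CIPK5 fell by 2.63 ± 0.75 on the log2 scale (adjusted p = 3.43e-08), the homeobox gene HOX4 fell by 2.31 ± 0.69 (adjusted p = 5.17e-08) and EXPB4 fell by 2.14 ± 0.97 (adjusted p = 1.55e-06), each in 8 of 8 accessions. DREB1B remained 21.5-fold above its level before cold, higher in 7 of 8 accessions, with -0.02 in Lixingeng. Its log2 change was 4.43, and 5.06 without Lixingeng, and that of ABA8OX1 was 4.98 without Lixingeng.

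JAZ13 and JAZ12 rose by a log2 of 2.94 and 2.88 at 24 h, MYB4 by 2.85, EL2 by 2.84 and MYB2 by 2.80. Another probe set of MYB4 rose by 0.38 and another of EL2 by 2.05. OST3 fell by 2.00, SWEET1B fell by 1.98, EXPB7 fell by 1.94, CIPK6 fell by 1.93 and EXPB11 fell by 1.83. OsPIP2;5, a plasma membrane aquaporin, fell by 1.79 ± 0.56, PMEI8 fell by 1.78, OsCASPL2C1 fell by 1.77 and the alpha-expansin gene EXP2 fell by 1.77 ± 0.41.

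In the jasmonate list 8 of 10 members rose at 24 h and 1 fell (8 and 2 adjusted over the list alone; 8 and 1 without the mixed arrays), with a mean change of 1.68 ± 0.69, higher in 8 of 8 accessions (exact sign-flip test, adjusted p = 0.0249; by camera, adjusted p = 0.381 with an estimated correlation). Of the other cold and stress regulators 8 of 12 rose and 0 fell (8 and 1 adjusted over the list alone; 9 and 0 without the mixed arrays), with a mean of 1.27 ± 0.44 (adjusted p = 0.0249 in the exact test; by camera, adjusted p = 0.000313 with the preset and 0.316 with an estimated correlation). WRKY71 rose 6.76-fold and DREB2B 4.07-fold. The DREB1/CBF list had 3 of 5 members higher (3 adjusted over the list alone; 3 without the mixed arrays) and a mean of 1.97 ± 1.03 (adjusted p = 0.0322 in the exact test; by camera, adjusted p = 0.0764 with the preset and 0.567 with an estimated correlation). DREB1E had a change of -0.03 and did not pass. DREB1C (-0.08) was at the background level at 24 h as well. The circadian clock list rose, with 4 of 6 members higher and 1 lower (4 and 1 adjusted over the list alone; 4 and 0 without the mixed arrays) and a mean of 0.56 ± 0.30 (adjusted p = 0.0249 in the exact test; by camera, adjusted p = 0.499 with an estimated correlation). PRR95 rose 2.34-fold, PRR1 2.29-fold, PRR37 by a log2 of 0.59 and GI 1.36-fold, PRR73 had a change of 0.07, and LHY fell by 0.16 (adjusted p = 0.0325), a call lost without the mixed arrays (-0.15) and without ZS97, Youmangzaogeng or Lixingeng (-0.11 to -0.15).

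Trehalose, raffinose and proline synthesis rose in 3 of 4 members (3 adjusted over the list alone; 3 without the mixed arrays), with a mean of 0.78 ± 0.46 (adjusted p = 0.0322 in the exact test; by camera, adjusted p = 0.115 with the preset and 0.566 with an estimated correlation). The median of the members was only 0.23, and TPP1 had the largest rise. TPP1 rose 6.52-fold, and the raffinose synthase gene RFS 1.25-fold. Of the LEA proteins and dehydrins, which protect cells during water loss, only the dehydrin LIP9 passed (1 of 7; 2 higher and 2 lower adjusted over the list alone). LIP9 rose by 0.84 ± 0.61 (adjusted p = 0.000212), its other probe sets by 0.06 and 0.10 without passing, and the list had adjusted p = 0.718 in the exact test. Of the chlorophyll synthesis genes 3 of 7 fell (1 rose and 4 fell adjusted over the list alone), among them PORA, which fell by 1.23 ± 0.84, and PORB, which fell by 0.74 ± 0.37, both protochlorophyllide reductases. The shift of that list, -0.37 ± 0.39, did not pass (adjusted p = 0.0746 in the exact test). Clade A phosphatases had 1 member higher and 3 lower of 6 (2 and 3 adjusted over the list alone; adjusted p = 0.185 for the list), with PP2C68 again lower, by -0.80. The cell division list had a mean of 0.06 ± 0.06 and passed (adjusted p = 0.0443 in the exact test), but the median of its members was -0.09 and camera gave adjusted p = 0.895 with the preset and 0.925 with an estimated correlation. Of its 3 members CDKB2;1, a mitotic kinase, rose by 0.86 and PCNA, the replication clamp, fell by 0.59 (1 and 2 adjusted over the list alone).

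Families read from symbols with a higher mean at 24 h included NAC factors (4 of 8; mean 0.99 ± 0.30; by camera, adjusted p = 0.256 with an estimated correlation), among them NAC068 at 6.76-fold and NAC45 at 4.16-fold. AP2/ERF factors rose in 5 of 10 members (1.22 ± 0.55; by camera, adjusted p = 0.381 with an estimated correlation), WRKY factors in 2 of 6 with 2 lower (0.79 ± 0.37) and calcium-dependent kinases in 8 of 20 with 4 lower (0.26 ± 0.12), led by CDPK1 at 4.07-fold and CPK5 at 3.06-fold. Calmodulins and calmodulin-like proteins rose in 8 of 26 and fell in as many (0.40 ± 0.18, with a median member at 0.05). In the exact test these 5 families had adjusted p = 0.0249. The last 3 did not pass by camera, with adjusted p = 0.665, 0.474 and 0.566 with an estimated correlation. Trehalose phosphate phosphatases, which also include TPP1, rose in 3 of 8 and fell in 1 (0.51 ± 0.33; adjusted p = 0.0322), with OsTPP4 at 2.45-fold. In the glutathione S-transferases (0.17 ± 0.15; adjusted p = 0.0322) only GSTU6 of 6 passed, at 1.85-fold, while its dim second probe set changed by -0.01. Stress-associated zinc finger proteins rose in 6 of 13 and fell in 2 (0.14 ± 0.13; adjusted p = 0.0443 in the exact test), with OsSAP11 at 2.34-fold and OsSAP4 lower by -0.75. These last 3 families did not pass by camera either, with adjusted p = 0.650, 0.474 and 0.627 with an estimated correlation.

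Families with a lower mean at 24 h were led by aquaporins, 17 of 25 lower and 2 higher, with a mean of -0.47 ± 0.13 (by camera, adjusted p = 0.381 with an estimated correlation). NIP1-1 fell by 2.02 ± 1.02 (adjusted p = 9.77e-06; lower in 7 of 8 accessions, with 0.30 in MH63). Expansins and xyloglucan enzymes fell in 15 of 30 and rose in 3 (-0.44 ± 0.10), CBL-interacting kinases fell in 11 of 24 and rose in 6 (-0.23 ± 0.07), with CIPK14 2.58-fold higher, and Aux/IAA proteins fell in 10 of 26 and rose in 3 (-0.14 ± 0.09). RNA helicases of the DEAD box fell in 2 of 3 (-0.47 ± 0.08), RH2 by -1.10, and histones fell in 3 of 5 (-0.45 ± 0.41), H2B.6 by -0.86. U-box and RING ubiquitin ligases fell in 7 of 13 and rose in 4 (-0.12 ± 0.07), a shift that did not pass with quantile normalization (-0.06). These 7 families had adjusted p = 0.0249 in the exact test. Only aquaporins passed by camera with the preset correlation. With an estimated correlation, adjusted p by camera was 0.381 for expansins, 0.828 for CBL-interacting kinases, 0.816 for Aux/IAA proteins, 0.499 for RNA helicases, 0.849 for histones and 0.816 for ubiquitin ligases. Cellulose synthases fell in 7 of 9 (-0.45 ± 0.24; adjusted p = 0.0322 in the exact test; by camera, adjusted p = 0.665 with an estimated correlation). Adjusted over the list alone, and without the mixed arrays after a slash, higher and lower members were 4 and 0 / 4 and 0 of the NAC factors, 5 and 1 / 6 and 0 of the AP2/ERF factors, 2 and 2 / 3 and 2 of the WRKY factors, 9 and 5 / 9 and 6 of the calcium-dependent kinases and 8 and 8 / 9 and 9 of the calmodulins. They were 3 and 1 / 5 and 1 of the trehalose phosphate phosphatases, 1 and 0 / 1 and 1 of the glutathione S-transferases, 6 and 3 / 6 and 3 of the zinc finger proteins, 2 and 17 / 2 and 17 of the aquaporins and 3 and 18 / 4 and 15 of the expansins. They were 6 and 13 / 5 and 12 of the CBL-interacting kinases, 4 and 11 / 5 and 10 of the Aux/IAA proteins, 0 and 2 / 0 and 2 of the RNA helicases, 0 and 3 / 0 and 3 of the histones, 4 and 7 / 3 and 6 of the ubiquitin ligases and 0 and 8 / 0 and 7 of the cellulose synthases.

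Of the 22 lists that passed at 24 h, 7 no longer did when single accessions were left out. This held for any accession but Lixingeng for DREB1/CBF factors (1.80 to 2.28 over all 8 such fits), any but Youmangzaogeng for cell division (0.05 to 0.07), any but IRAT109 for cellulose synthases (-0.52 to -0.42) and any but 9311 for glutathione S-transferases (0.14 to 0.20). It held for any but MH63 for stress-associated zinc finger proteins (0.11 to 0.17), trehalose phosphate phosphatases (0.46 to 0.59) and the trehalose, raffinose and proline list (0.70 to 0.92). DNA replication factors (-0.10) and cytosolic ribosomal proteins (-0.20) passed without MH63, and tubulins (-0.23) without IRAT109. In each of the 7 lists that were lost, the accession excepted was the only 1 of opposite sign. With fewer accessions the smallest exact p rises, so these losses do not show dependence on the accessions left out.

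The other lists did not pass at 24 h. Tubulins fell in 6 of 10 and rose in 1 (adjusted p = 0.0534), TUB7 being 1.65-fold higher, and cytosolic ribosomal proteins fell in 8 of 22 (adjusted p = 0.0651), RPL18 by -0.57. Photosynthesis proteins fell in 2 of 12 (adjusted p = 0.0893), OsPSAG by -0.71 and RCABP69 by -0.14, while 0 of 3 passed in the list of photosystems, light harvesting and Rubisco (adjusted p = 0.718). Another probe set of OsPSAG changed by -0.07 and did not pass. Heat shock proteins and factors rose in 10 and fell in 17 of 45 (adjusted p = 0.217), with HSF07 6.59-fold and HSF09 3.90-fold higher. DNA replication factors rose in 3 and fell in 8 of 28 (adjusted p = 0.0798), antioxidant enzymes rose in 3 and fell in 2 of 6 (4 and 2 adjusted over the list alone; adjusted p = 0.0798), and the sucrose enzymes rose in 2 of 9 (adjusted p = 0.898). Of the gibberellin list 1 of 4 rose, the DELLA repressor gene SLR1 by 0.44 (1 adjusted over the list alone; adjusted p = 0.898). Of the root-preferential genes 2 of 4 passed as lower (2 adjusted over the list alone), and the list had adjusted p = 0.192. The silicon channel gene LSI1 fell by 0.75. The iron transporter gene IRT1 (-0.22) read 34.8 to 71.4 over the 24 arrays and was not above the background on any of them, so the size of its change was not measurable. All of these list values are from the exact test. In lists too small to test, ACT1, the actin reference gene, fell by 0.31, 4CL3 of phenylpropanoid synthesis fell by 0.43 (1 of 2; 2 lower adjusted over the list alone) and NYC1, a chlorophyll b reductase of leaf senescence, rose by 0.57 (1 of 2). For ACT1 and NYC1 the counts adjusted over the list alone were 1 each. At 6 h no member of these 3 lists passed, with 2 lower for phenylpropanoid synthesis, 1 higher for leaf senescence and 0 for the reference gene adjusted over the list alone. In the abscisic acid list ABA8OX2 fell by 0.38 at 24 h (1 higher and 1 lower adjusted over the list alone). At both cold times 0 of 2 pathogenesis-related genes and 0 of 1 fatty acid desaturase passed (0 adjusted over the list alone), and 0 of 2 class III peroxidases and 0 of 1 trypsin and Bowman-Birk inhibitor passed. The mean and the median of the members differed in sign for LEA proteins and dehydrins (0.04 and -0.06), the gibberellin list (0.01 and -0.02), photosystems (-0.01 and 0.02), heat shock (0.04 and -0.008) and the sucrose enzymes (0.008 and -0.01). Camera ranked photosynthesis proteins, DNA replication factors and photosystems as higher against means of -0.06, -0.07 and -0.01.

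In all, 18914 probe sets (33.0%) changed at 24 h, 7591 higher and 11323 lower, and 1542 changed at least 2-fold, 748 higher and 794 lower. The mixed pair holds 1 before array and 1 array at 24 h, and without them the count was 21075 (9100 higher and 11975 lower). At 24 h the 75th percentile of intensity and the 3′ to 5′ ratio of the actin control were both lower than before cold in 8 of 8 accessions. Neither could be separated from the time in cold. With quantile normalization 9397 were higher and 9554 lower, 49.6% higher against 40.1%. It was 9985 without the accession as a block.

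The third question was which changes went on between 6 h and 24 h. PCL1 rose a further 7.31-fold (log2 change 2.87 ± 0.82, SD, n = 8; adjusted p = 1.65e-05), HSF03 5.35-fold, NAC068 3.61-fold, ACA7 3.55-fold and OsPP2C27 3.30-fold, each in 8 of 8 accessions. VIT1, a vacuolar iron transporter, fell by 1.09 ± 0.37 (adjusted p = 1.08e-05), the sugar transporter gene SWEET4 fell by 1.07, PMEI8 fell by 1.02, LOGL9, of the family that activates cytokinins, fell by 1.02 and the thioredoxin gene OsTrx10 fell by 0.99, each in 8 of 8. The DREB1/CBF list was lower at 24 h than at 6 h by a mean of -0.34 ± 0.28 (exact sign-flip test, adjusted p = 0.0365; by camera, adjusted p = 0.463 with the preset and 0.867 with an estimated correlation). Of its 5 members 1 passed, DREB1E, which fell by 0.38. DREB1B and DREB1A had changes of -0.09 and -0.51 and did not pass.

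Of the 35 lists, 11 were higher and 4 lower at 24 h than at 6 h. NAC factors had a mean of 0.57 ± 0.18 (adjusted p = 0.0342 in the exact test; by camera, adjusted p = 0.662 with an estimated correlation), with 3 of 8 members higher. The other cold and stress regulators had 0.47 ± 0.31 and the trehalose, raffinose and proline list 0.55 ± 0.29 (adjusted p = 0.0365 for both in the exact test; by camera, adjusted p = 0.662 with an estimated correlation for both). The circadian clock (0.32 ± 0.20), calcium-dependent kinases (0.23 ± 0.11) and trehalose phosphate phosphatases (0.34 ± 0.25) had adjusted p = 0.0365 in the exact test. WRKY factors (0.45 ± 0.27), clade A phosphatases (0.24 ± 0.13), gibberellin genes (0.10 ± 0.07), heat shock proteins and factors (0.08 ± 0.05) and cell division (0.15 ± 0.09, with a median member at -0.01) had 0.0342. The lower lists besides DREB1/CBF were aquaporins (-0.26 ± 0.14; 14 of 25 lower and 2 higher; adjusted p = 0.0342 in the exact test; by camera, adjusted p = 0.662 with an estimated correlation), RNA helicases of the DEAD box (-0.25 ± 0.11; 0.0342) and photosynthesis proteins (-0.06 ± 0.06; 0.0365). Apart from NAC factors, other cold and stress regulators, the trehalose, raffinose and proline list and aquaporins, none of these lists passed by camera with the preset correlation. With an estimated correlation, adjusted p by camera was 0.853 for the clock, trehalose phosphate phosphatases, clade A phosphatases and gibberellin genes, 0.867 for heat shock and cell division and 0.887 for photosynthesis proteins. It was 0.662 for calcium-dependent kinases, WRKY factors and RNA helicases. In most of these lists the larger part of the members did not pass. The counts of members for 24 h versus 6 h include the mixed arrays and are not given without them. Over all probe sets, members higher and lower were 5 and 0 of 12 other cold and stress regulators, 3 and 0 of 4 in the trehalose, raffinose and proline list and 2 and 1 of 6 clock genes. They were 7 and 2 of 20 calcium-dependent kinases, 3 and 0 of 8 trehalose phosphate phosphatases and 1 and 0 of 6 WRKY factors. They were 2 and 0 of 6 clade A phosphatases, 1 and 0 of 4 gibberellin genes and 8 and 6 of 45 heat shock proteins and factors (median member 0.02). They were 1 and 1 of 3 in cell division, 0 and 2 of 3 RNA helicases and 0 and 2 of 12 photosynthesis proteins. Adjusted over the list alone, members higher and lower were 0 and 1 for DREB1/CBF factors, 5 and 1 for other cold and stress regulators, 3 and 0 for the trehalose list, 2 and 1 for the clock, 2 and 1 for clade A phosphatases, 2 and 0 for gibberellin genes and 1 and 1 for cell division.

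The other 20 lists did not pass between 6 h and 24 h. Jasmonate genes (0.44 ± 0.48), chlorophyll synthesis (-0.27 ± 0.25) and stress-associated zinc finger proteins (0.09 ± 0.09) had adjusted p = 0.072, and expansins and xyloglucan enzymes (-0.11 ± 0.10) had 0.0513, in the exact test. The mean and the median of the members differed in sign for antioxidant enzymes (-0.03 and 0.001), U-box and RING ubiquitin ligases (-0.06 and 0.009), DNA replication factors (-0.04 and 0.003) and CBL-interacting kinases (0.004 and -0.01). Camera ranked antioxidant enzymes, DNA replication factors, AP2/ERF factors and tubulins as higher against means of -0.03, -0.04, -0.01 and -0.01. In all, 10350 probe sets (18.1%) differed, 4548 higher and 5802 lower, 447 of them at least 2-fold. The actin ratio was lower at 24 h than at 6 h in 7 of 8 accessions. Without the mixed arrays 14959 did (6854 higher and 8105 lower), with array weights 16000 and without the accession as a block 3252.

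The changes at the cold times were set against each other. Of the probe sets that passed, 1438 were higher at both times and 3587 lower at both, against 212 and 788 for independent lists of these sizes, and 30 went in opposite directions. Among genes ranked by the rule, which asks for the same direction in all 8 accessions, MYB2, EL2 and OsWRKY24 were ranked highest at both times. CIPK5, EXPB7, EXPB4, HOX4, EXPB11, CIPK6 and SWEET1B were ranked lowest at both. The changes in Lixingeng, whose before array is mixed, kept genes out of the ranking at 6 h, among them JAZ10 (-0.6) and ABA8OX1 (-0.65). JAZ9 (-0.77), CML16 (-0.79), CML15 (-0.36), MYB4 (-0.39), WRKY71 (-0.4) and DREB1G (-0.1) were kept out in the same way. At 24 h these changes kept DREB1B (-0.02) out, and DREB1A was not ranked there either. A further 527 probe sets passed only at 6 h, and 13859 only at 24 h. The correlation of log2 changes across probe sets, which are not independent replicates, was 0.821, against 0.496 for simulated unchanged groups that shared the before arrays, and the covariance was 0.0581 against 0.00278. With the 6 h changes from 4 accessions and the 24 h changes from the other 4, the correlation averaged 0.725 (0.614 to 0.794 over 70 choices) and the covariance 0.0548.

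The accessions were compared for the size of their response, with 1 array per accession and time and therefore no test. At 6 h the slope on the mean of the other accessions was 1.22 in Muguanuo, 1.09 in Youmangzaogeng, 1.06 in Geng87-304, 1.06 in ZS97, 1.04 in 9311, 0.983 in IRAT109, 0.973 in MH63 and 0.173 in Lixingeng. At 24 h it was 1.18 in Muguanuo, 1.18 in Geng87-304, 1.16 in Youmangzaogeng, 1.13 in IRAT109, 1.09 in ZS97, 0.961 in 9311, 0.622 in Lixingeng and 0.368 in MH63. The low values of Lixingeng at both times and of MH63 at 24 h came from comparisons that use the mixed arrays. Among named genes ABA8OX1 had a change of -0.65 in Lixingeng at 6 h, against 3.44 in the nearest other accession, and HOX4 had -0.81 in MH63 at 24 h, against -2.17.

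**Figure D3:**
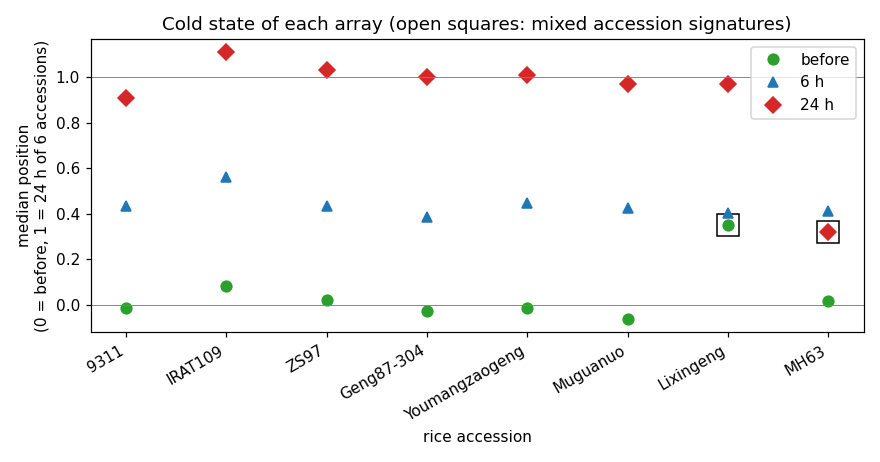
Median position of each of the 24 arrays on a scale from 0 (mean before state of 6 accessions) to 1 (their mean state at 24 h), over 2051 probe sets that changed at least 2-fold at 24 h in those 6, with symbols for time and open squares for the 2 arrays with mixed signatures. The other before arrays lay between -0.06 and 0.08, the 6 h arrays between 0.384 and 0.563 and the other 24 h arrays between 0.909 and 1.11, while the mixed arrays lay at 0.348 and 0.321.

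The last comparison was between the accessions, whatever the time in cold. Levels are means over the 3 times with the SD over those times, and those of Lixingeng and MH63 include the mixed arrays. OsC3H40, a gene of the CCCH zinc finger family, had the largest F (671). Its log2 level was 9.49 ± 0.14 in Youmangzaogeng (SD, n = 3), against 5.74 to 5.91 in the other 7 accessions. ICL, named for isocitrate lyase of the glyoxylate cycle, had 9.35 ± 0.49 in ZS97 against 5.71 to 6.83 elsewhere (F = 170). OsPP2C12, of the protein phosphatase 2C family, was lowest in IRAT109, at 6.44 ± 0.30, against 8.51 to 9.37 in the others, and rose 1.70-fold in cold at 24 h. YSL13, of the yellow stripe-like metal transporter family, was highest in IRAT109, at 9.20 ± 0.17, and Cht11, a chitinase gene, was lowest in ZS97, at 8.54 ± 0.40 against 10.30 to 12.10. OsC3H2 was low in IRAT109, ZS97 and Muguanuo, at 5.99 to 6.28, and at 8.35 to 9.58 in the other 5, and rose 2.56-fold at 24 h. Another probe set of OsC3H2, of the type shared between transcripts, averaged 10.05 over all arrays. Its levels by accession are not given here, so the contrast rests on a single probe set. TF1 lay at 5.63 to 5.72 in 9311, Lixingeng and MH63 and at 6.59 to 7.15 in the others. The remaining genes of the 10 were AO-1 (F = 127), with 7.56 and 7.76 in Lixingeng and MH63, HSF25 (F = 90.1), highest in ZS97 at 8.08, and cap2 (F = 75.7), highest in IRAT109 at 7.92.

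By the moderated F test 31100 of 57258 probe sets (54.3%) differed between accessions, covering 12355 of 17905 genes. Without the mixed arrays 34898 did. Probe sequences come from a reference cultivar, so a sequence difference under a probe can look like a difference in level.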

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

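The tests of the mixed arrays, of a weaker response and of time of day were chosen only after the result was seen, as was leaving the mixed arrays out of the test of probe sequence. The tests of probe sequence and of other splits were set before their own outcomes were seen, but after the counts of probe sets that passed for each time and for the accessions. A value stood out where its gap to the nearest accession, divided by the range of all 8, exceeded the 95% critical value of Dixon's test. Chance alone gives about 1 in 20 such values. Among named genes 38 of 292 sets of values stood out, 32 of them in Lixingeng or MH63, and among gene lists 16 of 86 did, 13 of them in Lixingeng.

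The size of the cold response of Lixingeng at 6 h, 0.173, stood out from the other accessions, of which the nearest was at 0.973. At 6 h the log2 changes of Lixingeng were apart for DREB1B (0.04), DREB1A (0.20), DREB1G (-0.10), MYB2 (0.70), MYB4 (-0.39), WRKY71 (-0.40), DREB2B (-0.44), ABA8OX1 (-0.65), LIP9 (-0.65), JAZ9 (-0.77), JAZ10 (-0.60), JAZ12 (-0.64), ACA7 (-1.36), CML15 (-0.36), CML16 (-0.79), H2B.11 (-0.15) and OsTPP4 (-0.49). At 24 h they were apart for DREB1B (-0.02), MYB2 (0.45), MYB4 (0.17), WRKY71 (0.21), ABA8OX1 (0.28), JAZ10 (0.03), CML15 (-0.04) and CML27 (0.16). In all of these but H2B.11 the other 7 accessions were higher than Lixingeng. The mean changes of lists in Lixingeng were apart at 6 h for DREB1/CBF factors (-0.05), other cold and stress regulators (-0.29), abscisic acid synthesis and breakdown (-0.35), jasmonate synthesis and JAZ repressors (-0.37), pathogenesis-related genes (0.94), photosynthesis proteins (-0.18), WRKY factors (-0.48), AP2/ERF factors (-0.06) and the trypsin and Bowman-Birk inhibitor (-4.00). At 24 h they were apart for DREB1/CBF factors (-0.23), abscisic acid synthesis and breakdown (0.10), AP2/ERF factors (0.03) and the trypsin and Bowman-Birk inhibitor (-2.22).

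In MH63 the changes at 24 h were apart for EXPB7 (-0.48), HOX4 (-0.81), CDKB2;1 (0.23), PCNA (0.07), NIP1-1 (0.30), OsPIP2;4 (0.15) and CPK5 (0.52). In the other accessions, PRR95 stood out in IRAT109 at 6 h (1.08) and 24 h (2.49), P5CS1 in IRAT109 at 24 h (0.41), PORB in ZS97 at 6 h (-0.43), AO-1 in ZS97 at 24 h (0.30) and SODCC2 in 9311 at 24 h (0.02). Among lists, expansins and xyloglucan enzymes stood out in Muguanuo (-0.48), RNA helicases of the DEAD box in Geng87-304 (-0.03) and CBL-interacting kinases in IRAT109 (-0.03), all at 6 h. No explanation was tested for these 9 values outside Lixingeng and MH63.

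The array labelled Lixingeng before cold and the array labelled MH63 after 24 h gave most of these values. RNA of both accessions mixed on both arrays would put each array near the middle on both accession signatures, and the median farthest from the middle was 0.585, so a mixture may explain the pair. Swapped labels would put each array near 1 on the signature of the other accession, which the same value of 0.585 argues against, and the labelled cold times would separate the arrays by the full 24 h change, which the share of -0.0407 of the change in the 6 other accessions argues against. A response to cold as weak as the slopes of Lixingeng would leave its other cold arrays near the before state, but those of Lixingeng (0.403 at 6 h and 0.969 at 24 h) and of MH63 at 6 h (0.412) lay within the range of the 6 others, the lowest at 0.899 of their mean. The accession signatures do not give the cold state of the mixed RNA, which is open. DREB1B and JAZ10 already stood near their 24 h level on the Lixingeng before array (changes of -0.02 and 0.03 to 24 h), although its median position was 0.348. Where a mixture arose is open, as is the response of MH63 at 24 h, for which no other array was analysed here.

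Changes at 6 h could reflect the time of day, to which the 24 h arrays had returned. To share no array, 6 h changes were taken from 3 of the 6 accessions without a mixed array and 24 h changes from the other 3, in 20 choices. Of the probe sets that passed at 6 h a median of 97.3% (91.4 to 99.1) had the same direction at 24 h, against 49.3 to 52.4% for all probe sets. This argues against a daily cycle back at its start by 24 h as the whole cause. The circadian clock list itself had not returned at 24 h (mean log2 changes of 0.28 to 1.12 over the accessions), so a cycle that did not return was not tested. The move to the chamber was shared by all cold arrays and was not separated from cold. For the 557 of 5582 that did not pass in the same direction at 24 h in all accessions together, time of day and cold cannot be told apart, because no untreated array at 6 h was analysed here. A part of time of day in the others is open as well.

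Differences between accessions could come from sequence differences under the probes. Of the 343 probe sets in which 1 accession stood at least 4-fold apart from the median of the other 7, without the mixed arrays, 136 (39.7%) were lower in it (95% confidence interval 34.4 to 45), with 65.9% in 9311 (29 of 44) and 23.4% in IRAT109 (25 of 107). A share of 50% or less had been set beforehand as speaking against probe sequence, but that bound was wrong, because an accession that matches the probes where the other 7 differ stands higher. Another probe set of the gene shared the direction for 11 of 29 lower ones (37.9%) and 19 of 33 higher ones (57.6%), a difference that was not tested. Probe sequence and a difference in level cannot be told apart for these probe sets, because the sequences of the accessions were not used here.

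Exchanging the labels of the compared times within accessions, 1 of 100 splits, the real one, passed as many probe sets at 6 h (5582, highest other 4282, with Lixingeng alone exchanged) and 1 of 100 at 24 h (18914, highest other 15807, with MH63 alone exchanged), so chance was excluded for both. For 24 h versus 6 h, 2 of 100 did (10350 for the real split, 10523 for the other), a share under 0.05. The other was the split that exchanged MH63 alone, whose 24 h array is 1 of the mixed pair, which points to a structure of the samples. Without the mixed arrays 14959 probe sets passed. Permuting accession labels within each time, 1 of 100 splits passed as many (31100, highest other 126). This excludes chance for the likeness of arrays with the same accession label. It does not separate the accession from a planting or pool of plants, which the labels do not give.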

How the results depend on the processing

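The fits without the 2 mixed arrays or without both of their accessions were chosen only after the data were seen. Over all alternatives, named genes had the same result in 3537 comparisons, no longer passed in 232, newly passed in 53 and reversed in 6, and gene lists did so in 807, 152, 19 and 2. For named genes a reversal was counted only where the main or the alternative value passed. A change of sign where neither passed counted as the same result. Leaving out each accession in turn gave 3828 to 5924 probe sets at 6 h, 16402 to 19649 at 24 h, 7515 to 12521 for 24 h versus 6 h and 23857 to 31540 for accessions, and 7 to 17 lists at 6 h and 15 to 20 at 24 h. The count was 7 when any 1 of the 7 accessions other than Lixingeng was left out and 17 without Lixingeng, and fewer accessions raise the smallest exact p. With 1 accession left out, named genes no longer passed in 127 comparisons, newly passed in 18 and reversed in 0, by limma.

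Against 5582 at 6 h, array weights gave 8854 probe sets, no replicate block for the accession 1530, an adjusted p under 0.01 gave 3093 and a 2-fold change 359. Against 18914 at 24 h, 1 probe set per gene gave 9921, no replicate block 9985 and a 2-fold change 1542. Against 10350 for 24 h versus 6 h, array weights gave 16000, 1 probe set per gene 6233, no replicate block 3252, an adjusted p under 0.01 gave 5769 and a 2-fold change 447. For accessions 12595 passed with 1 probe set per gene, adjusted separately, against 31100, since fewer probe sets were tested. Array weights were lowest for the mixed arrays, at 0.2 for MH63 at 24 h and 0.35 for Lixingeng before cold. The cause of the higher counts with weights was not tested. With quantile normalization the share that was higher at 6 h was 45.9% in place of 28.7%, and with equal medians 37.7%.

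Lists past the exact test, 15 at 6 h and 22 at 24 h, were 0 and 0 without both accessions, where the smallest exact p is 0.0312 before adjustment and 17 and 21 lists had an unadjusted p under 0.05. By camera, 12 lists at 6 h, 6 at 24 h and 4 for 24 h versus 6 h passed with the preset correlation and 0 of each with an estimated correlation, with 7, 2 and 1 at an unadjusted p under 0.05. The overlap correlation of 0.821 was 0.725 with different accessions. With quantile normalization the circadian clock, glutathione S-transferase and stress-associated zinc finger lists newly passed at 6 h (0.27, 0.14 and 0.09).

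Reversed values of genes came from other, dim probe sets of a gene, near the background, for NAC6 (-0.045 at 6 h, while a further probe set changed by 1.79, and -0.004 at 24 h), OsRH17 (0.039 and 0.056), CHLH at 24 h (0.067) and GSTU6 at 24 h (-0.013). Their mean log2 levels were 5.68 to 5.96. With the median over members taken within each accession and then averaged over the 8, in place of the mean, cell division (-0.0712) and heat shock (-0.0454) reversed at 24 h. The cause was not tested. For dim genes the offset and the background limit the change that can be seen.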

Other observations

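Further genes named by the rule changed at 24 h. The heat stress factor gene HSF10 rose 3.14-fold (adjusted p = 4.03e-08, limma, 8 accessions), and OsPP2C32 rose 5.53-fold and PMEI28 6.93-fold. The calcium-dependent kinase gene CDPK7 rose 2.51-fold and CPK20 rose 1.70-fold, and the CBL-interacting kinase gene CIPK25 fell by 0.97. The Aux/IAA genes IAA10 and IAA5 fell by 0.88 and 0.62, and the cellulose synthase genes CESA7, CESA9 and CESA4 fell by 0.84, 0.66 and 0.60.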
